A study of Mus musculus with 3 samples.

How the data were processed

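Total RNA-seq was run on chromatin-fraction RNA from 3 libraries of Lipid A stimulated macrophages, labelled biological replicates 1, 2 and 3. Per the labels the genome assembly was mm10, and the text files deposited with each library gave the GENCODE annotation M21. The aligner, the quantification programs and their versions are not given in the sources used here. Per the file headers, each library had a gene table and a transcript table with an expected count and a TPM column, under column names that RSEM writes, and a second transcript table with an estimated count and a TPM column, under names that kallisto writes. The estimated counts were used as deposited, and the TPM of the authors was scaled over all rows of a table, spike-in rows included. Replicates were not pooled. The labelled size range was 250 to 400, and the strand setting of the library and of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

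All 55536 gene identifiers were found in the annotation M21, from which symbols, gene types, transcript types and mm10 coordinates were taken. Rows that name no gene stayed out of every gene total: 96 ERCC rows with no count, a phiX row with 1.40%, 0.352% and 0.354% of expected counts in replicates 1, 2 and 3, and 26248 numbered rows of median length 73 with 9, 13 and 10 counts. Total expected counts including them were 13507963, 15406890 and 15868834. Library pairs were compared by a chi-square test of rounded counts, and chi-square per degree of freedom was 50.5, 20.3 and 51.0 for replicates 1 and 2, 1 and 3, and 2 and 3, so no library was a copy of another.

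Levels are TPM of the gene table, averaged over 3 libraries with the SD. List levels are medians of log2(TPM + 1) within each library, and a difference of 2 lists was taken within each library and tested with an exact two-sided sign-flip permutation test, whose smallest p is 0.25. As a description, each list's median was placed among 10000 random lists of nuclear coding genes matched on effective length in 10 bins. Shares are percents of a library's gene expected counts. Because TPM is a share of a total that short RNAs dominate, it understates coding genes. The spread between replicates was measured with edgeR 4.0.16 (estimateDisp, intercept only, TMM factors, filterByExpr) on expected counts rounded to whole numbers.

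For isoforms, the TPM of retained-intron and of protein-coding transcripts was summed per gene, and log2 of their ratio, with 0.5 added to each, was tested against 0 with limma 3.58.1 (intercept only, empirical Bayes with the variance trend on the mean summed TPM) in genes with transcripts of both classes and a mean summed TPM of at least 1. Adjusted p-values are Benjamini-Hochberg. Lists with at least 5 genes tested were compared with all other genes by camera at a preset correlation of 0.01 and again with an estimated correlation. On simulated data for 5560 genes, drawn with a coefficient of variation of 0.181, the isoform test recovered 73.0% of 74 2-fold changes, 100% of 74 4-fold changes and 100% of 49 8-fold changes, and 2.75% of its calls were false. Camera called 5 of 5 raised sets and 0 of 40 unchanged sets of 20 genes, none of the 40 with an unadjusted p under 0.05. Estimated sizes were too small, with medians of 0.81, 1.66 and 2.31 on the log2 scale for 2-fold, 4-fold and 8-fold changes. The simulated genes were independent, most were unchanged, and no read was assigned to the wrong isoform. These rates thus do not cover errors of isoform assignment or correlation between genes in the real data. In the simulated counts for the spread, a true coefficient of 0.2 was estimated as 0.201 over 12505 genes. R was 4.3.3, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

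The gene lists, the tests of the main results, most alternatives and the naming rule were fixed before the data were examined. That plan did not name the covariate of the variance trend. The alternative with the trend on the mean ratio, and the alternatives and closing tests said below to be so, were chosen after values were seen. There were 27 lists: immediate early, primary cytokine, late secondary, NF-kB feedback, interferon-stimulated, interferon induction, TLR4 signalling, macrophage, T cell, B cell, neutrophil, erythroid, fibroblast, endothelial, mast cell and basophil, dendritic, osteoclast, proliferation, nuclear noncoding, endoplasmic reticulum and secretory, cytosolic housekeeping, nuclear oxidative phosphorylation, cholesterol synthesis, LXR and efflux, mRNA decay control, transcription and splicing, and detained-intron genes. Ribosomal protein and histone lists were built from symbols, and the 7 lists from T cell to mast cell and basophil were joined as other cell types. The text may name, and names a selection of, the 10 coding and 10 other genes with the highest mean TPM, the 6 highest and 2 lowest members of each list, the 10 coding genes with the largest SD of log2(TPM + 1) at a mean count of at least 100, the 10 highest and 10 lowest isoform ratios past the threshold, list members past that threshold, and a few genes fixed by name. In the closing part, Gm42418 and CT010467.1 were taken up as neighbours of Gm26917, and no other gene was chosen outside the rule.

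Alternatives were the kallisto values, other pseudocounts, other filters on low values, means in place of medians, counts scaled to library size (CPM), TPM rescaled over coding and long noncoding genes, DESeq2 1.42.0 size factors, the mean TPM per annotated transcript, other forms of camera, and leaving out each replicate in turn. Intervals are 95% Wilson binomial intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. No groups could be compared, because the labels gave 1.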

Results

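The series measured RNA bound to chromatin in mouse bone-marrow-derived macrophages, strain C57BL/6J, after 60 minutes with 100 ng/ml Lipid A. Lipid A is the part of bacterial lipopolysaccharide that activates Toll-like receptor 4 (TLR4). The chromatin fraction holds nascent and partly processed transcripts, and the total RNA-seq libraries were depleted of ribosomal RNA. The labels gave 1 group of 3 biological replicates, with 1 µg of starting RNA for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3. Expected counts assigned to annotated genes were 13318395, 15352661 and 15812581 in replicates 1, 2 and 3. No unstimulated sample was analysed here, so the values below are levels after stimulation and comparisons between gene groups within the same libraries. Nothing in the labels said that the replicates came from separate animals, and all carried the same donor entry, so every p-value measures only the spread between these libraries, which may be technical.

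Nearly all expected counts fell on genes of the nuclear genome, which does not itself show where the RNA lay. Nuclear protein-coding genes took 63.2% ± 1.97 of expected counts (SD, n = 3) and nuclear genes that were neither coding nor pseudogenes took 36.2% ± 2.04. The noncoding share fell to 23.7% when 3 neighbouring genes on chromosome 17, described next, were taken out. Mitochondrial genes, whose RNA lies outside the nucleus, held 0.0403% ± 0.00911 of counts, and genes of cytosolic ribosomal proteins held 0.101% ± 0.0128. Replication-dependent histone genes held 0.00323% ± 0.000635. A single long noncoding gene, Gm26917 (mm10 chromosome 17, 39843013 to 39846341, plus strand), took 14.0% ± 2.88 of all counts. Malat1, a long noncoding RNA of nuclear speckles, took 9.98% ± 1.39, Xist, which coats the inactive X chromosome, took 1.48% ± 0.183, and Neat1, the scaffold of paraspeckles, took 1.31% ± 0.105. With kallisto these 3 shares were lower, at 6.54%, 0.994% and 0.875%. Ahnak, a coding gene with a very long exon, took 2.27% ± 0.459. By TPM the noncoding share was 77.4%, because TPM divides by length and short small nucleolar and Cajal body RNAs then held 41.3% of the total.

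**Figure D1:**
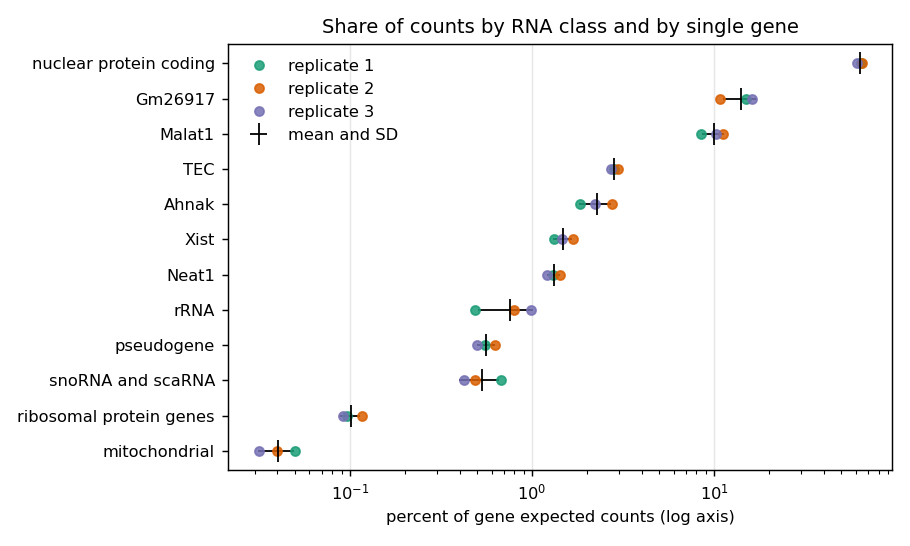
Percent of gene expected counts (log axis) in RNA classes and in single genes, with 1 point per replicate and the mean with its SD. Coding genes held 63.2% on average, Gm26917 alone 14.0%, and mitochondrial genes 0.0403%.

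At a TPM of at least 1 in all 3 libraries, 10143 genes were detected, of which 7870 were protein coding, and with kallisto the number was 18121. Another 708 were TEC genes, unspliced loci that the annotation holds as still to be tested by experiment, and 407 were antisense genes. Per library the number was 10645, 12104 and 11464 in replicates 1, 2 and 3. The coding gene with the highest mean was Lilr4b at 2926 TPM ± 755, next to its close paralog Lilrb4a at 2743 ± 527. Both are myeloid receptor genes on chromosome 10 whose reads could have been split wrongly between the copies. Tnfaip2, induced by tumour necrosis factor, stood at 2282 ± 164, Zeb2, a transcription factor of macrophage identity, at 1295 ± 264, and Malt1, a protease of NF-kB signalling, at 1228 ± 43.3 (SD, n = 3 each). Among other genes longer than 200 bases, the highest was Rmrp at 53710 TPM ± 13219, the RNA of the RNase MRP complex, which the annotation lists as 2 overlapping genes. Malat1 followed Gm26917 at 21825 TPM ± 3048, and Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, stood at 10127 ± 1443. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, held identical values in each library and cannot be separated.

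Immediate early genes stood at higher levels than late secondary genes on chromatin at 60 minutes. The list of 31 immediate early genes had a median log2(TPM + 1) of 4.58 ± 0.35 (SD over 3 libraries), with Dusp1, a phosphatase that restrains MAP kinases, at 287 TPM ± 75.3, Klf6 at 200 ± 31.8 and Atf3 at 105 ± 25.1. Fosl1 (0.517) and Egr3 (0.763) were the lowest members. The 25 late secondary genes had a median of 1.78 ± 0.18 and 12 of them were under a TPM of 1 in at least 1 library. Cxcl9 was at 0.0267 TPM and Mmp3 at 0.01, while C3 (139 ± 45.5) and Cd274, which encodes PD-L1 (124 ± 15.9), were the highest of that list. The difference between the medians was 2.80 ± 0.41 on the log2 scale and positive in 3 of 3 libraries (exact sign-flip permutation test, two-sided, p = 0.25, the smallest value that 3 libraries allow). Over members at a TPM of at least 1 in all libraries it was 1.13. The medians of both lists lay high among 10000 random coding lists of like length, at percentiles 100 and 98.1. That says little about the response, since the random lists held mostly silent genes, with medians of 0.38 and 0.30. Ribosomal protein genes lay at percentile 100 and histone genes at 99.95.

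Primary cytokine and chemokine genes stood above interferon-stimulated genes. The 22 primary cytokine genes had a median of 7.12 ± 0.17, equal to 138 TPM, and 21 were detected in all libraries. Il1b led with 661 TPM ± 88.6, then Cxcl2 with 452 ± 131 and Tnf with 428 ± 75.8, and Ccl5 stood at 199 ± 66.6. Csf3 (0.48) and Cxcl3 (2.75) were the lowest. The 47 interferon-stimulated genes had a median of 4.95 ± 0.46, equal to 29.8 TPM, with Parp14 at 451 ± 96.6, Rsad2, an antiviral enzyme, at 426 ± 254 and Ifih1, the RNA sensor MDA5, at 342 ± 214. Tgtp1 and Ifit1bl1 were at 0.1 and 0.0767. The difference between the medians was 2.17 ± 0.43 and positive in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25). It depended on the scaling by length, and with log2(CPM + 1) in place of TPM it was 0.70. Ifnb1, the interferon gene induced first through TLR4 in macrophages, reached 25.1 TPM ± 11.5, from 237, 121 and 324 counts. Interferon induction genes had a median of 5.33 ± 0.21, led by Ikbke (613 ± 23.8) and Tbk1 (147 ± 17.9), while Ifna4 and Ifnl2 had no count in any library. A count of 0 allows up to 3 counts per library, which is 0.225, 0.195 and 0.19 CPM in replicates 1, 2 and 3. Such limits cover counting error only.

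Genes of the NF-kB feedback list stood above the genes of the TLR4 signalling chain itself. That list also holds NF-kB targets that are not feedback regulators, such as Icam1 and Sod2. Its 37 genes had a median of 6.84 ± 0.14 and every member was at a TPM of at least 1 in all libraries. Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, was at 800 TPM ± 135, Ikbke at 613 ± 23.8, Icam1 at 469 ± 45.8 and Sod2 at 468 ± 62.9. The lowest were Birc2 (15.1 ± 0.197) and Cyld (12.1 ± 0.962). The 32 TLR4 signalling genes had a median of 4.34 ± 0.24, with Tank at 368 ± 27.6 and Cd14, the lipopolysaccharide co-receptor, at 158 ± 52.2, while Tlr4 itself was at 5.52 ± 1.95 and Map2k6 at 0.31 ± 0.0755. The difference was 2.49 ± 0.20 and positive in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25). Among other genes named in advance, Il10 was at 51.2 TPM ± 21.3 and Il12b at 45.9 ± 28.8. Il6 was at 4.43 ± 2.12 from 191, 58 and 208 counts, and Nos2 at 1.05 ± 0.645 from 78, 22 and 82 counts. With kallisto the mean log2(TPM + 1) was 4.26 for Tlr4 and 2.25 for Nos2, against 2.66 and 0.98. These low levels thus depended on the quantifier. Il10 was at 6.36 against 5.60, while Cd14, Il6 and Il12b stayed within their SD.

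**Figure D2:**
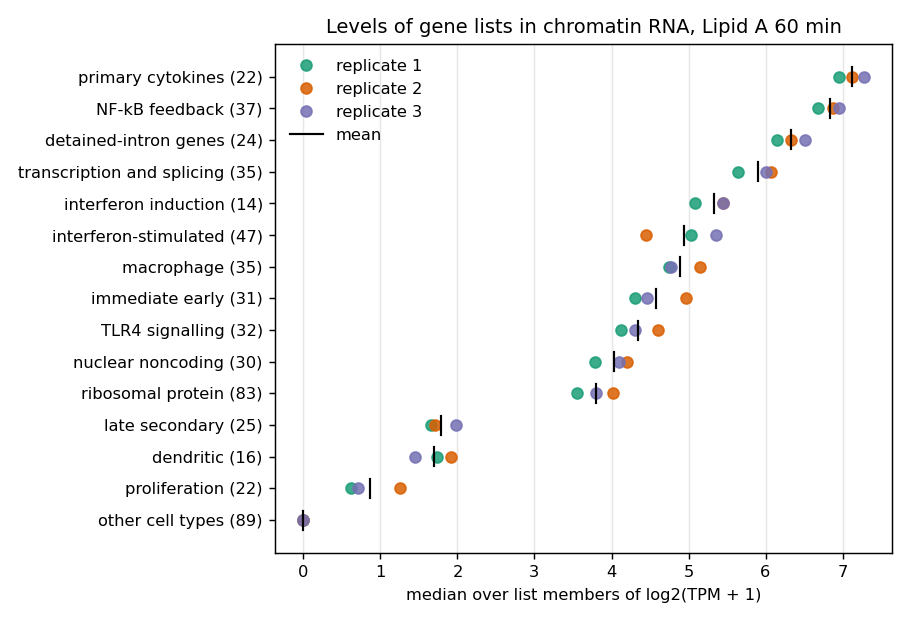
Median log2(TPM + 1) of each gene list, with the number of members in brackets, 1 point per replicate and a bar at the mean. Primary cytokine genes (7.12) and NF-kB feedback genes (6.84) were highest, and replicate 2 was the lowest library for interferon-stimulated genes (4.45, against 5.03 and 5.36).

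Macrophage markers stood well above markers of other cell types. All 35 macrophage markers were at a TPM of at least 1 in all libraries, with a median of 4.89 ± 0.23. Gpnmb, a lysosomal glycoprotein, was at 1164 TPM ± 341, Tfec at 508 ± 106, Ptprc, which encodes CD45, at 454 ± 55.5, and the mannose receptor gene Mrc1 at 195 ± 25.7. C1qa (2.57 ± 0.747) and Fcgr1 (1.82 ± 0.564) were lowest. Of 89 markers of 7 other cell types, 4 were at a TPM of at least 1 in all libraries and 40 had no count in any. Some low values depended on the quantifier, since with kallisto the mean log2(TPM + 1) was 4.69 for Cd3d, 3.41 for Thy1, 2.41 for Ebf1 and 2.00 for Ms4a1, against 0, 0.10, 0.02 and 0.03. The 4 detected were Vwf (45.6 ± 6.01), Csf3r (31.1 ± 0.939), Cd5 (3.02 ± 0.961) and Kdr (1.95 ± 0.234). By list, the medians were 0 in each library for T cell, B cell, neutrophil, erythroid, and mast cell and basophil markers, 0.04 on average for fibroblast markers and 0.02 for endothelial markers. The median difference between macrophage markers and the other cell types was 4.89 ± 0.23 and positive in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25). Its size was set by the pseudocount, since the second median was 0, and a pseudocount of 0.1 gave 8.17, while members at a TPM of at least 1 in all libraries gave 1.40. Dendritic cell markers had a median of 1.70 ± 0.23, led by Cd83 (176 ± 28.8), which activated macrophages also express, and osteoclast markers 0.66 ± 0.24. Proliferation genes had a median of 0.86 ± 0.35, and 4 of 22 were detected in all libraries, among them Mki67 at 94.5 ± 13.6.

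Nuclear noncoding RNAs were compared with ribosomal protein genes, whose mature mRNA is cytosolic, to describe the fraction. The 30 noncoding genes ranged from Rmrp, Malat1 and Rn7sk down to Meg3 and Rian, which had no count in any library, with a median of 4.03 ± 0.21. With kallisto Rian was at a mean log2(TPM + 1) of 4.40 and Meg3 at 0.49, so those zeros depended on the quantifier. The 83 ribosomal protein genes had a median of 3.79 ± 0.23, with Rpl23 at 76 ± 13.8 and Rpl10 at 66.1 ± 18.4. The difference of 0.23 ± 0.06 was positive in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25). The medians were thus close. With the kallisto values the mean difference was 0.04 and at least 1 library was below 0 (lowest -0.08), and with log2(CPM + 1) the difference was 1.85.

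The common biological coefficient of variation between the libraries, from edgeR, was 0.181 over 12505 genes, and 0.125 without replicate 2. Pearson's r of log2(TPM + 1) across 11537 genes, which are not independent replicates, ranged from 0.944 for replicates 1 and 2 to 0.958 for replicates 1 and 3. Among 6140 coding genes with a mean expected count of at least 100, the median SD of log2(TPM + 1) was 0.24. The 10 most variable of these included 4 genes of the antiviral and secondary response. Cmpk2 was at 74.1, 17.7 and 99.2 TPM in replicates 1, 2 and 3, its neighbour on chromosome 12, Rsad2, at 450, 160 and 667, Ifih1 at 323, 139 and 566, and Il12b at 67.3, 13.1 and 57.4. Ifnb1 was likewise lowest in replicate 2, at 23.6, 14.3 and 37.2. Tnf (344, 491 and 448), Cxcl2 (355, 602 and 401) and Tnfaip3 (656, 922 and 823) were highest there, while Ccl5 (191, 137 and 269) and Il6 (4.93, 2.11 and 6.26) were lowest. Coding genes as a whole were also higher in replicate 2, by a median of 0.23 in log2(TPM + 1) against the other libraries. Taken in the same way, the median was -0.29 in replicate 1 and 0.06 in replicate 3, so a low replicate 1 deviated most. By expected counts, nuclear coding genes held 63.9%, 64.6% and 60.9% in replicates 1, 2 and 3. No stronger response is therefore read from Tnf, Cxcl2 and Tnfaip3. The others of the 10 were mt-Co2, B430305J03Rik, Tpd52l2, Zfp236, Incenp and Mpp7. Of these, mt-Co2 had 314 counts in replicate 2 and none in replicates 1 and 3, but its mean log2 level was 5.03 with kallisto against 1.82, so those zeros depended on the quantifier. B430305J03Rik was at 0 with kallisto.

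**Figure D3:**
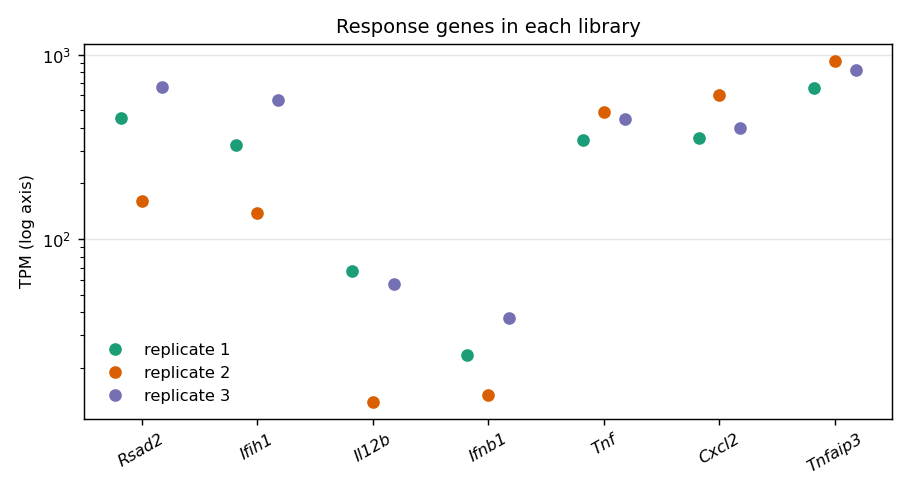
TPM of 7 response genes in each library (log axis), with 1 point per replicate. Rsad2, Ifih1, Il12b and Ifnb1 were lowest in replicate 2, and Tnf, Cxcl2 and Tnfaip3 were highest there. Most coding genes were also slightly higher in TPM in replicate 2 than in the mean of the other libraries.

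Retained-intron isoforms were compared with coding isoforms of the same gene, as the measure in these tables nearest to unfinished splicing. Over coding genes, transcripts annotated as protein coding held 48.2% ± 1.49 of TPM and retained-intron transcripts 39.3% ± 1.65, with 8.87% ± 0.213 in processed transcripts and 3.60% ± 0.218 in transcripts subject to nonsense-mediated decay. Of 5601 genes tested with limma, 1987 had retained-intron isoforms above coding isoforms at a Benjamini-Hochberg adjusted p under 0.05, 1784 had the opposite, and 1830 passed in neither direction. The median log2 ratio was 0.08. The near-even split depended on the scaling, and with the mean TPM per annotated transcript the numbers were 2204 and 1121 and the median 0.38. With kallisto in place of the other quantifier the first number was 3201, and 271 of the genes called by both had opposite signs, so the ratio of a single gene depended on the quantifier. The 10 highest and 10 lowest genes named below kept their sign and stayed past the threshold with both, but the size of several ratios changed.

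The highest ratio was that of Lilrb4a, at 11.93 (SE 0.23, limma adjusted p = 2.77e-08), with 2735 TPM in retained-intron and 0.213 in coding isoforms. Its paralog Lilr4b was at 5.56 (SE 0.18), and both are uncertain because reads could have been split wrongly between them. Rsrp1, an arginine and serine rich protein gene, followed at 7.21 (SE 0.15) with 175 TPM against 0.723, then Psd at 6.40, Slc27a1 at 5.92 and the cyclin gene Ccnl1 at 5.34 (SE 0.36). Spaca6, Rps18, Srp54b and Map1s completed the 10, between 4.85 and 5.17. Rps18 and Srp54b had 0 TPM in coding isoforms in each library. Of the short sequence words in the coding transcripts of Rps18, 86.2% also occurred in other genes. Coding reads of Rps18 could thus have been assigned elsewhere, and its ratio is uncertain too. For Srp54b shared sequence was not measured. With kallisto the ratio was 2.49 for Srp54b and 5.48 for Rps18. At the other end, Pde4b, a cyclic AMP phosphodiesterase induced by NF-kB, had a ratio of -7.28 (SE 0.15, limma adjusted p = 2.92e-08), with 78.1 TPM in coding isoforms and 0 in retained-intron isoforms in each library. Plxna1 was at -7.04, Wdfy3 at -6.47, Gtf2ird2 at -6.05 and Ccdc88b at -5.83. Cog5, Rprd1b, Xpot, Cul3 and Plec lay between -5.44 and -5.19. The pseudocount of 0.5 TPM sets the size of a ratio where an isoform class is at 0.

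Response genes split in both directions. Of 27 NF-kB feedback genes, 13 had retained-intron isoforms higher, 11 coding isoforms higher and 3 neither. Nfkb1 (2.75, SE 0.14), Sod2 (2.29, SE 0.16), Malt1 (2.17, SE 0.15) and Tnfaip3 (1.15, SE 0.16) were on the retained-intron side. Nfkbia, which encodes the inhibitor IkB-alpha (-3.50, SE 0.13), Nfkb2 (-2.90, SE 0.14), Cflar (-2.56, SE 0.13) and Irf1 (-1.24, SE 0.14) were on the coding side. Among 11 primary cytokine genes 5 were higher for retained introns, with Cxcl10 at 1.61, and 3 for coding isoforms, with Il1rn at -2.90. Among 27 interferon-stimulated genes the split was 13 and 6, with Oasl2 at 3.13 and Oas2 at -4.58. Among 9 immediate early genes it was 3 and 4, with Dusp1 high (276 TPM against 10.5) and Gadd45b at -1.74. Among 22 TLR4 signalling genes it was 6 and 7, and among 18 macrophage markers 3 and 10, with Csf1r at -3.16, Mrc1 at -3.18 and Apoe at -4.81. The median ratio and the mean ratio had opposite signs in immediate early, primary cytokine, NF-kB feedback and TLR4 signalling genes, so no direction is claimed for those lists. Adjusted over the list alone, these splits were 13 and 11, 6 and 3, 13 and 6, 3 and 4, 6 and 7, and 3 and 10.

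Of 19 lists tested with limma's camera at a preset correlation of 0.01, 3 had higher ratios than the other genes and none had lower. Ribosomal protein genes had a median ratio of 1.08 ± 0.13 (SD of the library medians, n = 3) against 0.07 in the other genes (adjusted p = 0.00207), with 40 of 64 members higher for retained introns and 7 lower. Transcription and splicing factors had 1.11 ± 0.13 (adjusted p = 0.024), with 20 of 30 higher and 5 lower, among them Tra2a (4.04), Srsf3 (2.72), Brd2 (2.56) and Srsf5 (2.40). Genes known for detained introns, which stay in polyadenylated nuclear RNA, had 0.88 ± 0.20 (adjusted p = 0.024), with 12 of 21 higher and 3 lower, led by Rsrp1, Tra2a, Srsf11 (3.52) and Clk1 (2.55). These 2 lists share 10 genes. Each of the 3 was above the other genes in 3 of 3 libraries. With an estimated correlation no list passed: adjusted p = 0.736 for ribosomal protein genes, adjusted p = 0.872 for transcription and splicing factors and adjusted p = 0.823 for detained-intron genes. None passed with the kallisto values either. The estimated correlation was 0.119 for transcription and splicing factors, but -0.0067 for ribosomal protein genes and -0.023 for detained-intron genes, below the preset 0.01. Correlated members thus do not account for the higher p-values of the latter lists. With an estimated correlation camera also takes its degrees of freedom from the libraries, which are only 3. Adjusted over the list alone, the counts were 40 and 7, 20 and 5, and 12 and 3. The list with the lowest median was that of macrophage markers, at -0.78 ± 0.03, which did not pass (camera adjusted p = 0.151).

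**Figure D4:**
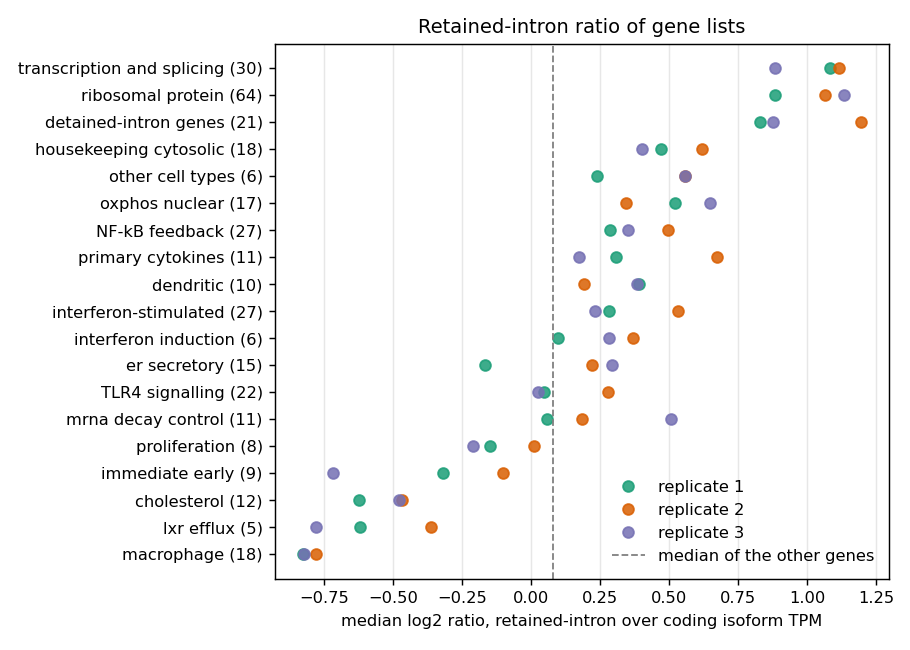
Median log2 ratio of retained-intron to coding isoform TPM in each list, with the number of genes tested in brackets, 1 point per replicate and the median of the other genes as a dashed line. Transcription and splicing factors, ribosomal protein genes and detained-intron genes lay highest and macrophage markers lowest, at -0.78.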

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

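Signals outside the main measurement were found in rows that name no mouse gene. The phiX row, the genome of a phage used as a sequencing control, held 189559 counts in replicate 1, which was 1.40% of that library's total (95% Wilson interval 1.40 to 1.41). It held 54216 counts in replicate 2, or 0.352% (0.349 to 0.355), and 56243 in replicate 3, or 0.354% (0.352 to 0.357). The numbered rows held 9 counts in replicate 1, 13 in replicate 2 and 10 in replicate 3, summed over 26248 rows. Neither kind of row entered a gene total.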

How the results depend on the processing

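The mean of each list difference stayed positive under every alternative run, but with kallisto nuclear noncoding minus ribosomal protein was below 0 in at least 1 library (lowest -0.08). Of 99 alternative values of the main results 71 stayed within the spread between libraries, or within 1.5 times for counts. Some of the 71 could not have moved. A mean with 1 library left out always lies within the SD of all libraries, and camera does not use the variance trend. With the kallisto values, 18121 genes were detected, immediate early minus late secondary was 1.97, macrophage minus other cell types 5.39, nuclear noncoding minus ribosomal protein 0.043, 3201 genes had retained-intron isoforms higher, and 0 lists passed camera. Means in place of medians gave 1.92 for immediate early minus late secondary, 1.48 for primary cytokines minus interferon-stimulated, 2.74 for NF-kB feedback minus TLR4 signalling and 1.36 for nuclear noncoding minus ribosomal protein. With log2(CPM + 1) the cytokine difference was 0.70, the macrophage difference 5.46 and the noncoding difference 1.85. A pseudocount of 0.1 gave a macrophage difference of 8.17, and TPM rescaled over coding and long noncoding genes gave 6.55. Members at a TPM of at least 1 in all libraries gave 1.13 for immediate early minus late secondary, 1.40 for the macrophage difference and 1.10 for the noncoding difference. That filter removes the silent members by construction; for the other settings the cause was not tested.

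Detection gave 15465 genes at a TPM of at least 0.1 and 5441 at 5. The noncoding share was 77.4% by TPM and, in an alternative chosen after seeing the data, 23.7% without Gm26917, CT010467.1 and Gm42418. A summed TPM of at least 5 tested fewer genes and left 1116 genes with coding isoforms higher and 1 list past camera. The mean TPM per annotated transcript left 1121 genes with coding isoforms higher and 0 lists, and 362 genes called by both measures had opposite signs. An estimated correlation left 0 lists. Leaving out each replicate in turn gave a coefficient of variation from 0.125 (without replicate 2) to 0.206. The numbers of genes and lists stayed within 1.5 times. For list differences and shares, leaving out 1 library cannot move a mean beyond the SD, so it tests nothing there. Single-gene isoform ratios of the 20 named genes kept their sign and call in 180 of 180 alternatives, but not their size. The 20 were picked for extreme ratios in these data. Settings that change only the filter or the variance trend leave the ratio as it is, so its sign could not move there. Plec went from -5.19 to -0.87 with the mean TPM per annotated transcript, and with kallisto Plxna1 went from -7.04 to -2.44, Cul3 from -5.25 to -2.34 and Srp54b from 5.08 to 2.49. Over 11537 genes, 30.6%, 26.8% and 23.4% differed by over 2-fold between the quantifiers in replicates 1, 2 and 3. Those genes had a mean TPM of at least 1. Of 253 named genes 33 did so in the mean of log2(TPM + 1), in a comparison chosen after seeing the data. The figures are not alike, since many named genes lay near 0, where such a change is hardly possible. Of the 253, 167 were counted as moved beyond their SD, which an SD of 0 always gives. Of 30 list levels, 28 were counted as moved beyond their spread with kallisto, also chosen after seeing the data. A list with an SD of 0 was counted as moved whatever its kallisto value. That held for T cell, B cell, neutrophil, erythroid, mast cell and basophil, and other cell types. Depth limits genes with few counts, such as Nos2 (78, 22 and 82 counts).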

Other observations

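The tests of a weaker response as a whole, of a ribosomal RNA precursor and of the number of annotated transcripts were chosen only after the result was seen. Levels of lists that belong to no comparison above are given next. Detained-intron genes had a median log2(TPM + 1) of 6.33 ± 0.19 (SD, n = 3) and transcription and splicing factors 5.91 ± 0.24, led by Rbm39 (933 TPM ± 79.5), Hnrnpa2b1 (495 ± 40.5) and Srsf5 (488 ± 76.5). Cytosolic housekeeping genes had 4.96 ± 0.29, with Fth1 at 356 ± 69.9, and mRNA decay control genes 4.08 ± 0.18, with Zfp36, which encodes tristetraprolin, at 56.9 ± 3.69. LXR and efflux genes had 4.15 ± 0.20, with the cholesterol exporter gene Abca1 at 377 ± 81.5. Cholesterol synthesis genes had 2.03 ± 0.13, with Insig1 at 40.1 ± 4.43. Endoplasmic reticulum and secretory genes had 3.01 ± 0.23, nuclear oxidative phosphorylation genes 2.27 ± 0.35 and histone genes 0.49 ± 0.21.

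Of the 708 detected TEC genes, 525 lay wholly within a coding gene on the same strand (74.2%), 91 within a coding gene on the opposite strand only, and 92 within none. Their median TPM was 5.54, 5.23 and 3.91.

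Interferon-stimulated genes were lower in replicate 2 than in replicates 1 and 3, while most coding genes were slightly higher there. The list median of log2(TPM + 1) in replicate 2 minus the mean of the other libraries was -0.23, with 35 of 44 members below 0, against a median of 0.23 over 10376 coding genes with a mean count of at least 10. Of 10000 random lists matched on mean level, 0% were as low, which argues against a scaling or depth difference of all genes. After a trend on GC content and transcript length was removed the deviation was -0.25. Relative to all coding genes the interferon-stimulated list was shifted by -0.46. The shift was -0.16 for primary cytokine, -0.10 for NF-kB feedback and 0.07 for immediate early genes. A response to Lipid A that was weaker as a whole was taken to shift the primary cytokine and NF-kB feedback lists at least 0.5 times as much. That was not met, but the bar was set after the values were seen. How a weaker response would divide between the lists was not measured. The primary cytokine list lay at percentile 5.18 of its matched random lists, and at 1.87 after that trend was removed. Placed in the same way, that list lay at percentile 2.84 in replicate 1 and at 100 in replicate 3. Its low place in replicate 2 thus also depended on the high replicate 3 it was set against. A weaker response in replicate 2 is neither shown nor excluded by these values. Late secondary genes were also low relative to all coding genes (-0.40). Proliferation genes (0.23), macrophage markers (0.21), ribosomal protein genes (0.19) and cytosolic housekeeping genes (0.13) were high. The starting RNA also differed between the libraries, and no other biological explanation was tested, so the cause stays open.

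Gm26917 took 14.0% of all counts, and with its neighbours CT010467.1 and Gm42418, which overlap each other, the share was 16.9% in replicate 1 (95% Wilson interval 16.9 to 17.0), 13.3% in replicate 2 (13.3 to 13.3) and 19.1% in replicate 3 (19.1 to 19.1). The first 20 bases of 18S ribosomal RNA, read on the strand of Gm26917, began 12 bases after its end, at position 39846353 of chromosome 17 (mm10), inside CT010467.1, which the annotation types as rRNA on the opposite strand. Gm26917 may thus be the spacer at the start of a ribosomal RNA precursor, which depletion aimed at mature ribosomal RNA could leave in place. Reads shared with other annotated transcripts are argued against, since 0% of its 31-base words occurred in transcripts of other genes. Unannotated ribosomal DNA copies were not searched.

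Ribosomal protein genes had the lowest camera p for high retained-intron ratios, with a median of 1.08 against 0.07 in the other genes, but did not pass with an estimated correlation (limma adjusted p = 0.736). Small nucleolar RNA genes inside the retained introns do not account for all of it, since 42 members without any had a median of 0.75 (limma camera p = 0.0134, unadjusted; p = 0.0992 with an estimated correlation). The number of annotated retained-intron transcripts was close, with a mean of 2.75 per gene against 2.69 in the other genes tested. Coding transcripts were fewer, at 3 against 3.63, so the number of annotated transcripts is argued against only weakly. With the mean TPM per transcript the list was still higher, at an unadjusted camera value of 0.0186. It did not pass after adjustment over the lists (limma camera adjusted p = 0.276). Coding reads lost to pseudogenes and other genes may contribute and cannot be told apart: 10 members with under 20% of the 31-base words of their coding transcripts in other genes had a median of 0.20 against 0.07 in the other genes, and 54 members with more had 1.19, but 10 genes are too few to decide.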
